A study of Bos taurus with 34 samples.

How the data were processed

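The samples are mammary gland RNA of cows in mid-lactation. Per the labels, 12 cows received 4 diets in a Latin square: low forage (LF), high forage (HF), low forage with sunflower oil (LFSO) and high forage with whole rapeseeds (HFRS). The arrays used here put 2 diets of the same cow on one slide, with 18 arrays of LFSO against LF from 9 cows and 16 arrays of HFRS against HF from 8 cows. Per the labels, total RNA was extracted and DNase treated, and cDNA was labelled directly with Cy3 or Cy5. Each cow's pair of samples was hybridised on 2 arrays with the dyes exchanged. The channel labels of each array set the direction of its ratio. The arrays do not show by themselves that the dyes of every pair were exchanged as labelled. With the mean dye profile subtracted, swapped arrays correlated at a median r of 0.0178. The profile was subtracted at full size from each array, while the slopes of the arrays on it ran from 0.632 to 1.33. Some dye effect therefore stays in this r, which does not measure what the arrays share beyond dye. For a pair that was not exchanged, the average of its arrays would not measure the diet.

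Per the file headers, the deposited spot intensity values of each channel were quantified with ImaGene 6.0.1 and are not background subtracted. The deposited value table of the series holds log2 ratios that the authors normalized by a method the sources used here do not give. Set against the scanner values, its ratios run as supplemented over control diet on all 34 arrays and the median of each array is 0. The correlation with the ratios computed here was 0.821 to 0.957 per array across probes. The table was used as an alternative.

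Each array has 19200 spots, of which 2436 are controls, and 8382 non-control probes that are spotted 2 times. Gene symbols came from the array's annotation: 6840 probes have 1 symbol, 93 have several and 1449 have none in the table used, with 6535 distinct symbols. Entrez identifiers of 6820 of the single-symbol probes were found in the RefSeq table of assembly ARS-UCD2.0, which changed 0 symbols. The array files name no genome build, so no coordinates are given.

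Signal means were corrected with background medians by limma's normexp with an offset of 50, and log2 ratios were normalized by global loess within each array, with control spots at weight 0. Spots marked by ImaGene as poor or empty were left out. The 2 spots of a probe were averaged, and then the 2 swapped arrays of a cow, which gave 1 value per probe and cow; a value was missing if either array lacked it. This average removes a dye effect that is equal on both arrays. Tested probes were measured in at least 6 cows of each comparison. They were also detected, in either channel, above the background median plus 2 background SD on at least 0.5 of all arrays.

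LFSO vs LF, HFRS vs HF and their difference were tested in one limma model of the 17 cow values with a coefficient per comparison, lmFit and eBayes with an intensity trend, which gives 15 residual degrees of freedom. The 2 diets of a cow share an array, so cow is already the block within each comparison. The replicate numbers of the 2 comparisons are different cows, and 7 cows are in both. For the difference, cow was therefore tried as a replicate block, as differences within the 7 shared cows (0 probes) and as a random block (16 probes). HF vs LF was tested as differences within those 7 cows between channel intensities after loess and Aquantile normalization, which compares values from different slides. Adjusted p-values are Benjamini-Hochberg values per comparison and were called under 0.05; all tests are two-sided.

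The 28 gene lists were tested with limma's camera in its pre-ranked form, since some cows lack values for some probes. The preset correlation was 0.01, with 1 probe per gene (the brightest) and at least 5 tested genes in a list. Camera with an estimated correlation and fry were run on genes measured in every cow. The lists cover milk proteins, lactose, fatty acid, triacylglycerol and cholesterol synthesis, fatty acid uptake and oxidation, desaturation, the milk fat globule, lipogenic regulators, mitochondria, ribosomes, stress, inflammation, interferon, proliferation, involution and the cell types of the gland. Several genes stand in more than 1 list, such as CD14 and LALBA. A further list of 30 milk genes was always to be named; 23 were tested, and SCD, ACACA, PPARG, LPIN1, FADS1, FADS2 and CSN2 are not analysed here.

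The naming rule took, with 1 probe per gene, the 10 genes of smallest p in each direction (5 for the difference and for HF vs LF), up to 4 members of smallest p per list, and the milk genes. Symbols that are only locus numbers were counted and not named. For 219 genes with several tested probes, effects had the same sign in 117 in LFSO vs LF and 113 in HFRS vs HF. The design, the tests, the lists, the naming rule and the first set of alternatives were set before the data were examined, except the pre-ranked form of camera, which was chosen once values were seen to be missing.

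The alternatives set in advance changed the background correction, the loess, the signal statistic, the filter on dim probes, the weights of arrays and the prior of the spread. They also used the authors' table, each of the 17 cow values left out in turn, all arrays with a dye coefficient, the feeding period as covariates and subsets of the cows. Batch was taken from the 4 image folders named in the file headers, as a model term and within a folder. Both arrays of a cow value lie in the same folder. Alternatives chosen after seeing the data kept spots left out above, removed each cow value's regression on the dye profile, or kept only the 9 of 17 cow values whose swapped arrays correlated above 0 after the dye profile was removed. They also left out both values of each of the 7 shared cows. Values with and without the image folder and period terms, and the SE by brightness, were compared after seeing the data too.

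The whole procedure was tested on simulated data in which changes were added to the measured values of 200 probes per comparison. All 200 were changed at once, each by the same amount in every cow. So many changed probes ease the adjusted threshold, so the shares run high for data in which few probes change. Of those at log2 0.25, 86% were recovered in LFSO vs LF, 86% in HFRS vs HF and 68% in the difference. At log2 0.5 the shares were 100%, 100% and 94%. Over 10 further draws of the changed probes, those at log2 0.25 were recovered in 84% to 92%, 72% to 90% and 50% to 74%. In LFSO vs LF 109 probes without an added change passed beside them, against 11 without any added change. The list test recovered the oxidative phosphorylation list, shifted by 1 unit of the z statistic, in 91% of 200 shuffled runs. Without a shift any list was called in 1.5% of them. That list is the largest, with 40 tested genes, and shuffling over genes breaks their correlation. The shares therefore do not carry over to smaller lists or to correlated genes. R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.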

Results

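The series holds 34 arrays of mammary gland RNA from cows in mid-lactation. Each array carried 2 RNA samples of one cow, one taken on a control diet and the other on the same diet with a lipid supplement. In 9 cows a low-forage diet (LF) was compared with the same diet plus sunflower oil at 4 g per 100 g of dry matter (LFSO). In 8 cows a high-forage diet (HF) was compared with the same diet plus whole rapeseeds at 13.9 g per 100 g of dry matter (HFRS). Every cow's pair of samples was hybridised on 2 arrays with the dyes exchanged, which makes 17 cow values, and 7 cows appear in both comparisons. The median spot signal per array was 456 to 910 in Cy3 and 598 to 1600 in Cy5, and 95.2% to 99.3% of probes were detected on an array. The number of arrays limits the precision.

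Dye bias was larger than the diet effects in these arrays. The standard deviation over probes was 0.18 (log2) for the part of the ratio that follows the dye, 0.06 for the mean LFSO effect and 0.05 for the mean HFRS effect. The ratios of the 2 swapped arrays of a cow, turned to the same direction, correlated across probes between -0.633 and -0.0937, below 0 in all 17 cow values. With the dye profile subtracted at full size from each array the median correlation was 0.0178, and it was above 0 in 9 of 17. Some dye effect stays in these values, since the slopes of the arrays on the profile ran from 0.632 to 1.33. The 2 spots of a probe on an array correlated between 0.755 and 0.915.

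**Figure D1:**
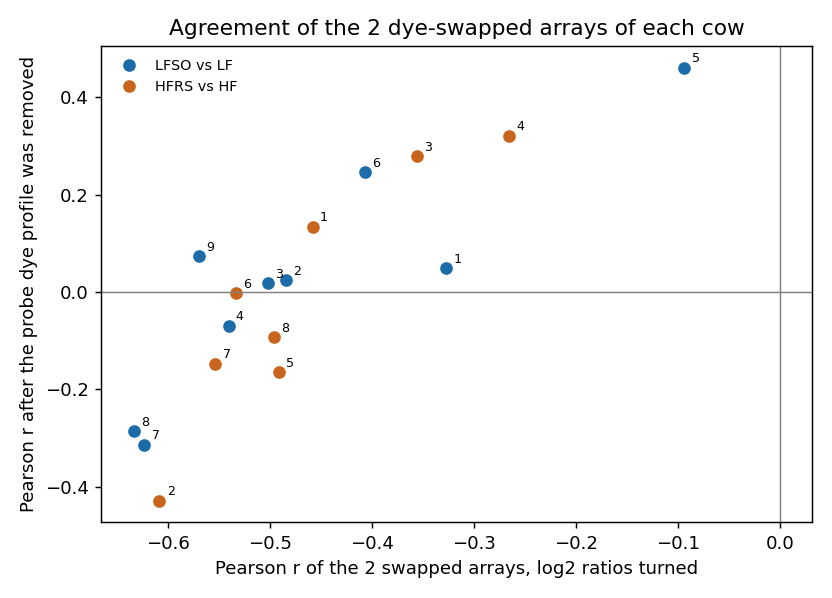
Agreement of the 2 dye-swapped arrays of each cow, with 1 point per cow value and the replicate number beside it. The horizontal axis is Pearson's r across probes of the log2 ratios turned to supplemented over control diet, and the vertical axis is the same r after the probe dye profile was removed. All 17 points lie left of 0, and 9 lie above 0 on the vertical axis.

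The comparison of LFSO with LF asks which mammary genes respond to sunflower oil on a low-forage diet. TALDO1, an enzyme of the pentose phosphate pathway, rose by 0.27 ± 0.05 on the log2 scale (SE, n = 8 cows) and was higher in 8 of 8 cows (limma, adjusted p = 0.0381). AARSD1, which clears wrongly charged alanine tRNA, rose by 0.26 ± 0.05 (SE, n = 9) and was higher in 9 of 9 cows. SNED1, a matrix glycoprotein, rose by 0.24 ± 0.05 in the mean and was higher in 8 of 9 cows. FDFT1, the squalene synthase of cholesterol synthesis, fell by 0.16 ± 0.03 and was lower in 9 of 9 cows. NSUN5, a methyltransferase of ribosomal RNA, fell by 0.18 ± 0.03 and was lower in 9 of 9 cows.

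The other named genes past the threshold were GPRIN2 at 0.23 ± 0.05 (9 of 9 cows higher), the calcium-permeable channel TRPM2 at 0.21 ± 0.04 (8 of 9), the aldehyde dehydrogenase ALDH3B1 at 0.17 ± 0.03 (9 of 9) and the deubiquitinase USP12 at 0.15 ± 0.03 (9 of 9). The probes were Bt00007286 for TALDO1, Bt00003756 for AARSD1, Bt00006155 for SNED1, Bt00008293 for FDFT1, Bt00006104 for NSUN5, Bt00005698 for GPRIN2, Bt00000811 for TRPM2, Bt00003499 for ALDH3B1 and Bt00004247 for USP12. Adjusted p lay at 0.0478 for USP12, FDFT1 and NSUN5 and at 0.0482 for GPRIN2, TRPM2, ALDH3B1, AARSD1 and SNED1. In all, 11 of 7226 probes passed limma's test at an adjusted p under 0.05, 9 higher and 2 lower. One of the 11 has only a locus number as its symbol and one has no symbol in the annotation used. A second FDFT1 probe, the brighter one, stood at -0.03 ± 0.06, with 5 of 9 cows lower, and did not pass, so the probes of this gene disagree. FDFT1 was named after its values were seen. None of the 7226 probes reached a 1.5-fold change, and the largest size was 0.47 on the log2 scale. At an unadjusted p under 0.05 there were 874 probes (12.1%), 466 higher and 408 lower, where chance alone would give 361.

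**Figure D2:**
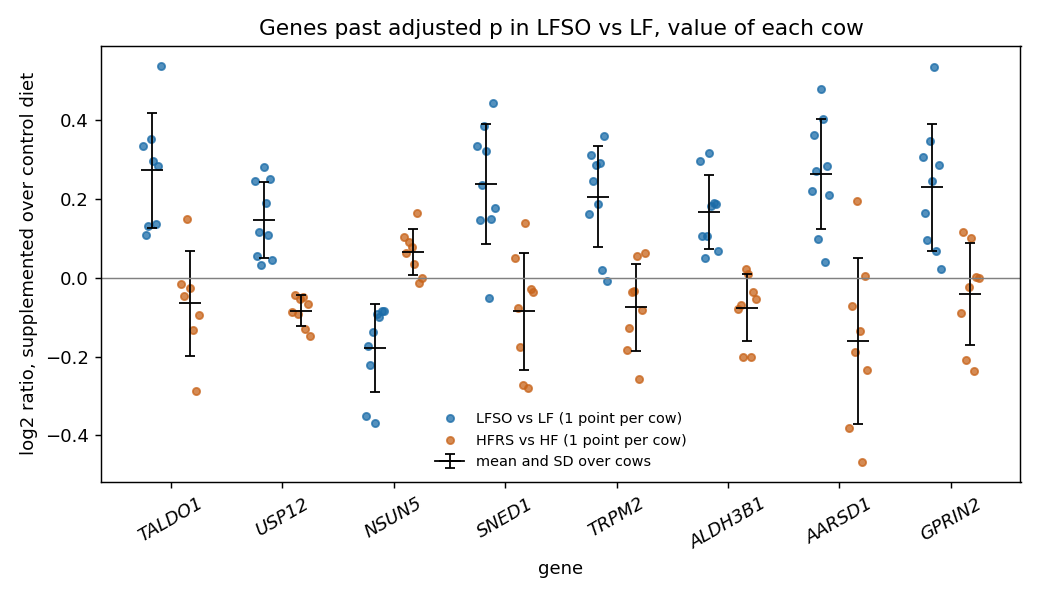
Values per cow of 8 named genes past the threshold in LFSO vs LF, with 1 point per cow on a log2 scale and the mean and SD over cows in black. FDFT1, whose brighter probe did not pass, is not shown. Blue points are LFSO vs LF (9 cows, 8 for TALDO1) and orange points are HFRS vs HF (8 cows, 7 for TALDO1). GPRIN2, ALDH3B1, AARSD1 and USP12 lie above 0 in 9 of 9 LFSO cows, and NSUN5 lies below 0 in 9 of 9.

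Just short of the threshold on the higher side were RAI14 at 0.15 ± 0.03 (8 of 9 cows higher, adjusted p = 0.0587), TMEM79 at 0.20 ± 0.04 (9 of 9, 0.0590) and the splicing factor RBM5 at 0.17 ± 0.04 (8 of 9, 0.0686). On the lower side the mitochondrial fission enzyme DNM1L stood at -0.24 ± 0.05 (8 of 9 cows lower, adjusted p = 0.0686) and the phospholipid flippase ATP10A at -0.20 ± 0.04 (8 of 9, 0.0537). STYX stood at -0.18 ± 0.04 and SSPO at -0.18 ± 0.04, each lower in 9 of 9 cows. LRFN3, RFC2, PTPN23, POLR3F and TRAK1 lay between -0.17 and -0.12, each lower in at least 8 of 9 cows.

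The genes of milk fat synthesis did not pass over all probes in LFSO vs LF. DGAT1, which makes the last step of triacylglycerol synthesis, stood at 0.18 ± 0.05 and was higher in 8 of 9 cows (adjusted p = 0.103 over all probes and 0.0255 over the 23 milk genes chosen in advance). FASN, the fatty acid synthase, stood at -0.11 ± 0.05 and was lower in 8 of 9 cows (adjusted p = 0.347); without LFSO replicate 5 its value was -0.15. BTN1A1 and XDH, which coat the milk fat globule, stood at 0.13 ± 0.04 and 0.08 ± 0.06, and the lipid droplet coat PLIN2 at 0.08 ± 0.05. The lipogenic regulator SREBF1 stood at -0.05 ± 0.03, INSIG1 at 0.01 ± 0.04 and THRSP at -0.02 ± 0.04. LPL, which frees fatty acids from blood lipids, stood at -0.05 ± 0.06, CD36 at -0.01 ± 0.04, FABP3 at 0.07 ± 0.08 and ACSL1 at -0.03 ± 0.05. LPL stood at -0.12 without LFSO replicate 5, CD36 at 0.0061 without replicate 4 and ACSL1 at 0.01 without replicate 6. The acetate and citrate enzymes ACSS2 and ACLY both stood at -0.04, and the acyltransferases GPAM and GPAT4 at 0.11 ± 0.08 and -0.07 ± 0.03. The milk protein genes CSN1S1, CSN3, LALBA and PAEP lay between 0.01 and 0.07. Without LFSO replicate 5 LALBA stood at -0.03. SLC2A1, STAT5A and PRLR stood at 0.07, -0.05 and 0.01. Of these 23 genes, 13 were higher and 10 lower; 0 passed over all probes, 1 (DGAT1) passed adjusted over the list alone, and 3 had an unadjusted p under 0.05.

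**Figure D3:**
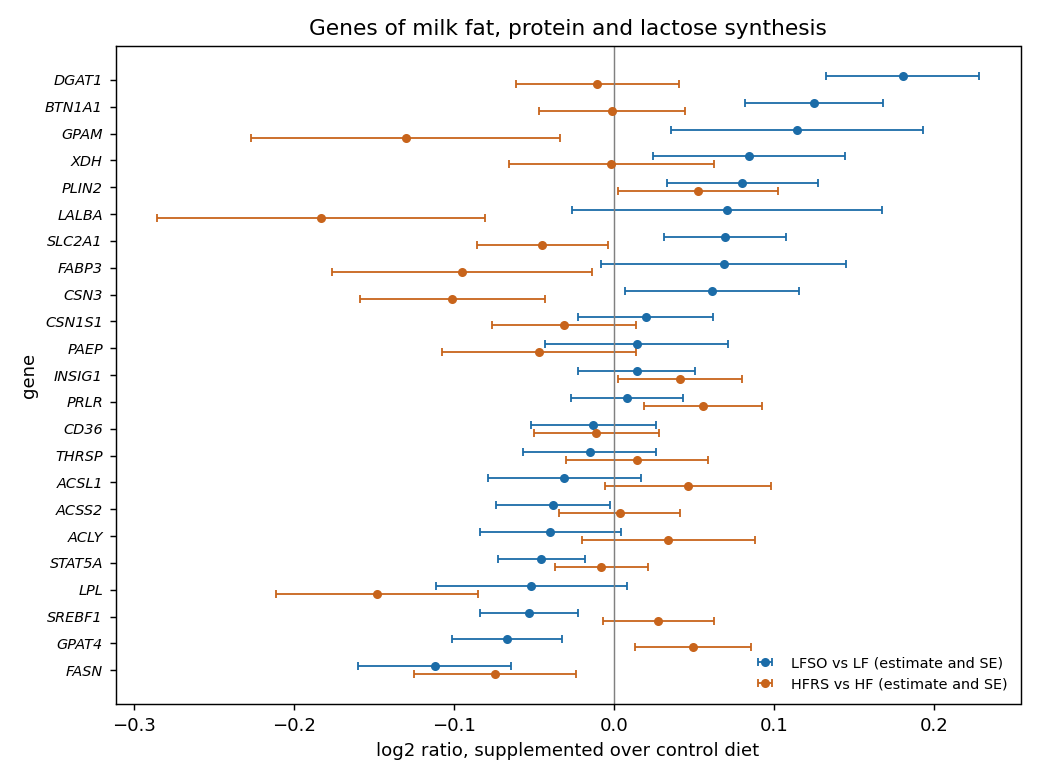
Estimates of the 23 genes of milk fat, protein and lactose synthesis in LFSO vs LF (blue, 9 cows) and HFRS vs HF (orange, 8 cows), as log2 ratios of supplemented over control diet on the horizontal axis with their SE as bars. The estimates lie between -0.11 and 0.18 in LFSO vs LF and between -0.18 and 0.06 in HFRS vs HF.

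No gene list passed in LFSO vs LF. By limma's camera, 0 of 26 lists passed, the smallest adjusted p was 0.531, and 1 list had an unadjusted p under 0.05. That list was secretory epithelial markers, with 7 of 9 genes higher and a median of 0.07. At an unadjusted p under 0.05 it held 3 higher genes and 1 lower gene. Its examples CLDN3, a tight junction protein, and ERBB3, a receptor of the lactating gland, stood at 0.13 ± 0.05 and 0.11 ± 0.05, each higher in 6 of 9 cows. Of the lipogenic regulators 11 of 15 were lower (median -0.04), with SCAP, the carrier of SREBP, at -0.07 ± 0.04. Of the genes of de novo fatty acid synthesis 7 of 9 were lower (median -0.04). Of the triacylglycerol genes 5 of 7 were higher (median 0.02), and of the milk fat globule and lipid droplet genes 7 of 10 (median 0.04). The fatty acid uptake genes split evenly, 5 of 10 higher (median 0.0030). Fatty acid oxidation split too, 7 of 14 lower (median -0.0023), with ACADVL at -0.10 ± 0.04 and CPT2 at -0.14 ± 0.05. Of the cholesterol genes 5 of 9 were lower (median -0.0063, mean 0.01). Of the milk protein genes 6 of 10 were higher (median 0.01, mean -0.02), and of the lactose and glucose uptake genes 6 of 10 (median 0.01, mean -0.0013). Desaturation and elongation, with 3 tested genes, and erythrocyte markers, with 1, were too small to test. TECR, which makes the last step of elongation, stood at 0.06 ± 0.04, and the haem enzyme ALAS2 at -0.04 ± 0.04.

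Genes of stress and immunity in LFSO vs LF held the other members that passed adjusted over the list alone. PRDX1, a peroxidase of the oxidative stress list, stood at 0.18 ± 0.05 and was higher in 8 of 9 cows (adjusted p = 0.0881 over all probes and 0.0107 over the list alone). CD14, the co-receptor for bacterial lipopolysaccharide, stood at 0.16 ± 0.04 and was higher in 8 of 8 cows (0.0783 over all probes, 0.00520 over the inflammation list, 0.00676 over the myeloid list). IFI27 of the interferon list stood at -0.13 ± 0.04 and was lower in 8 of 9 cows (0.147 over all probes, 0.0423 over the list). With DGAT1 in the triacylglycerol list that makes 5 list members over the list alone and 0 over all probes. An adjustment over 1 list does not correct for the 26 lists, so some members are likely to pass by chance. The list medians were 0.01 for oxidative stress (9 of 16 genes higher), 0.01 for inflammation (6 of 10, mean -0.02), 0.02 for interferon (11 of 17) and -0.03 for myeloid markers (7 of 13 lower, mean 0.02). Medians of the remaining lists were -0.02 for immediate early and heat shock genes (13 of 21 lower), -0.01 for endoplasmic reticulum stress (9 of 16 lower), -0.01 for proliferation (9 of 16 lower), -0.02 for involution and cell death (9 of 17 lower), -0.0032 for cytosolic ribosomal proteins (19 of 36 lower) and -0.0041 for oxidative phosphorylation (23 of 40 lower). Among cell types they were 0.03 for fibroblast and matrix markers (8 of 11 higher), -0.02 for adipocyte markers (8 of 10 lower), -0.0064 for myoepithelial markers (4 of 7 lower, mean 0.0056), -0.01 for endothelial markers (5 of 7 lower, mean 0.01), -0.02 for lymphocyte markers (7 of 11 lower, mean 0.0012) and 0.01 for class II antigen presentation (4 of 7 higher). In the cholesterol, myeloid, myoepithelial and endothelial lists camera's direction was up while the median was below 0. In the inflammation, milk protein and lactose lists it was up while the mean was below 0, and in the lymphocyte list it was down while the mean was above 0. With an estimated correlation the smallest adjusted p was 0.788, and with fry 0.330 (0.902 for its mixed test), each over 23 lists.

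The count of 11 probes in LFSO vs LF depended on single cow values. It was 0 without LFSO replicate 1, 4, 5 or 8 and without HFRS replicate 2, 5 or 7, since the comparisons share one estimate of the spread; it was 1 without LFSO replicate 6, 3 without LFSO replicate 3 or HFRS replicate 8, 5 without LFSO replicate 2 and 20 without LFSO replicate 7. Without both values of a shared cow it was 0 to 42, the highest without the cow of LFSO replicate 7 and HFRS replicate 4. With the scanner's image folder as a batch term it was 0 (830 at an unadjusted p under 0.05; smallest adjusted p = 0.0583). TALDO1 stood at 0.27 ± 0.05 before and 0.26 ± 0.05 after that term, USP12 at 0.15 ± 0.03 both times and SNED1 at 0.24 ± 0.05 and 0.23 ± 0.04. Over the 11 probes the log2 values with the term were 0.939 to 1.03 times those without it. The SE was larger in 10 of 11 (median 1.04 times) and 12 residual degrees of freedom were left of 15. The adjusted p-values had been 0.0381 to 0.0482, and the unadjusted p-values rose in 10 of 11. Over all probes the SE was 1.02 times that without the term in the median. The 11 were picked for a small p, which tends to rise in a refit, and why the calls ended was not tested. The supplemented diet came 1 period after the control diet in 6 of 9 cows and 3 periods before it in the other 3. With feeding period as covariates the count was 0 (788; smallest adjusted p = 0.0559). TALDO1 then stood at 0.30 ± 0.05, USP12 at 0.14 ± 0.03 and FDFT1 at -0.14 ± 0.03, and over the 11 probes the log2 values were 0.892 to 1.09 times those without the term. The SE was larger in 9 of 11 and the unadjusted p-values in 10. With the LFSO cow values fitted alone the means were the same, 8 residual degrees of freedom were left and the count was 0 (843; smallest adjusted p = 0.0963). Within image folder 1, which holds 3 of the 9 cows, the count was 0 as well (357 of 7222 at an unadjusted p under 0.05).

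The comparison of HFRS with HF asks the same of whole rapeseeds on a high-forage diet, and no gene passed. The genes of smallest p among those lower were ITGB2, the beta chain of leukocyte integrins, at -0.24 ± 0.05 (SE, n = 8; 7 of 8 cows lower), the GTP-binding protein DRG1 at -0.13 ± 0.03 (8 of 8) and the potassium channel KCNK12 at -0.16 ± 0.04 (7 of 8), each with an adjusted p of 0.696. IFT27 and B9D1, which serve primary cilia, stood at -0.16 ± 0.04 (6 of 8) and -0.26 ± 0.08 (8 of 8). ERCC6L2 stood at -0.23 ± 0.06 (7 of 8), SIX5 at -0.22 ± 0.06 (7 of 8), and BIN2, EXTL1 and DHX38 between -0.16 and -0.11. Among those higher were FDPS, the farnesyl diphosphate synthase of the mevalonate pathway, at 0.13 ± 0.03 (8 of 8 cows higher, adjusted p = 0.854), FCSK, which salvages fucose, at 0.12 ± 0.03 (8 of 8), BTD, which recycles biotin, at 0.11 ± 0.03 (8 of 8) and the kinase MAP3K14 at 0.18 ± 0.05 (7 of 8). ANKRD1, CHRD, CKS1B, RTTN, USP21 and RPUSD2 lay between 0.09 and 0.18, each higher in at least 7 of 8 cows.

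By limma 0 of 7226 probes passed in HFRS vs HF, and 374 had an unadjusted p under 0.05 (5.18%), 117 higher and 257 lower, where chance alone would give 361. In simulated data with changes put into this comparison, 86% of those at log2 0.25 and 100% of those at 0.5 were recovered (72% to 90% and 96% to 100% over 10 further draws). These shares hold for 200 probes changed at once and do not exclude changes of that size in a few genes. In the measured values ITGB2 at -0.24 ± 0.05 did not pass. The count was 0 with image folder as a batch term (479 at an unadjusted p under 0.05) and within image folders 1 and 4 (646 and 261), which hold 3 of the 8 cows each. It was 1 without HFRS replicate 4, with or without the same cow's LFSO value.

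None of the 23 milk genes passed in HFRS vs HF, over all probes or adjusted over the list alone; 1 had an unadjusted p under 0.05. That gene was LPL at -0.15 ± 0.06, lower in 7 of 8 cows (adjusted p = 0.902). LALBA, a subunit of lactose synthase, stood at -0.18 ± 0.10 with 4 of 8 cows lower. Over 46 other settings its value ran from -0.43 to 0.09. Kappa-casein (CSN3) stood at -0.10 ± 0.06 with 7 of 8 lower, CSN1S1 at -0.03 ± 0.04 and PAEP at -0.05 ± 0.06. FASN stood at -0.07 ± 0.05, GPAM at -0.13 ± 0.10, FABP3 at -0.09 ± 0.08 and SLC2A1 at -0.04 ± 0.04. DGAT1 stood at -0.01 ± 0.05, BTN1A1 at -0.0010 ± 0.05, XDH at -0.0015 ± 0.06, PLIN2 at 0.05 ± 0.05, GPAT4 at 0.05 ± 0.04 and SREBF1 at 0.03 ± 0.03. CD36, INSIG1, THRSP, ACSS2, ACLY, ACSL1, STAT5A and PRLR lay between -0.01 and 0.06.

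By camera 0 of 26 lists passed in HFRS vs HF (smallest adjusted p = 0.846, 0 lists at an unadjusted p under 0.05). Of the lipogenic regulators 11 of 15 were higher (median 0.01), of the secretory epithelial markers 7 of 9 lower (median -0.03) and of the oxidative phosphorylation genes 27 of 40 lower (median -0.02), with UQCRC1 of complex III at -0.12 ± 0.05. FDPS passed over the cholesterol list alone (adjusted p = 0.00852, 8 of 8 cows higher) as the 1 list member to do so, against 0 over all probes. With no correction over the 26 lists, 1 such member can arise by chance. TM7SF2 of the same list stood at -0.13 ± 0.05. The list direction was up while the median was below 0 for endoplasmic reticulum stress (-0.00094), involution and cell death (-0.0088) and class II antigen presentation (-0.0069). For triacylglycerol synthesis it was up with a mean of -0.01, and for endothelial markers up with a mean of -0.0075. With an estimated correlation the smallest adjusted p was 0.805, and with fry 0.646 (1 for its mixed test).

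The difference between the supplement effects, LFSO vs LF minus HFRS vs HF, tests whether a gene responded differently to the diets. ERCC6L2, a helicase of DNA repair, differed by 0.44 ± 0.08 on the log2 scale and was higher in 7 of 7 cows present in both comparisons (limma, adjusted p = 0.0360). AARSD1 differed by 0.42 ± 0.08 (6 of 7 cows, 0.0360), the lipid phosphatase MTMR4 by 0.42 ± 0.08 (7 of 7, 0.0492), USP12 by 0.23 ± 0.04 (7 of 7, 0.0360) and ALDH3B1 by 0.24 ± 0.05 (7 of 7, 0.0492). NSUN5 differed by -0.24 ± 0.05 (7 of 7 lower, 0.0492). The leukocyte integrin ITGB2 differed by 0.35 ± 0.07: it stood at 0.11 in LFSO vs LF and at -0.24 in HFRS vs HF. In all, 16 of 7226 probes passed, 15 higher and 1 lower. Each of the 15 was above 0 in LFSO vs LF and below 0 in HFRS vs HF. The choice by a large difference makes opposite signs likely, and none of the 15 passed in HFRS vs HF. The other names were TALDO1, SNED1, TRPM2, PARPBP, IFT27, TET2 and EEF1B2, between 0.22 and 0.34; like ITGB2 they fall outside the naming rule for this difference and were named after their values were seen. The brighter of 2 TET2 probes stood at -0.01 ± 0.05, so the probes of this gene disagree; without HFRS replicate 5 the called one stood at 0.21 ± 0.05 against 0.24 ± 0.05 with it and did not pass (adjusted p = 0.0894). At an unadjusted p under 0.05 there were 926 probes. Short of the threshold, SSPO stood at -0.24 ± 0.05 (7 of 7 cows lower, adjusted p = 0.0644), MAP3K14 at -0.27 ± 0.07, BTD at -0.18 ± 0.05 and TRAK1 at -0.15 ± 0.04.

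By camera 0 of 26 lists passed in the difference (smallest adjusted p = 0.292, 2 lists at an unadjusted p under 0.05). Of the secretory epithelial markers 7 of 9 were higher (median 0.13), with CLDN4 at 0.18 ± 0.07 and KRT18, a luminal keratin, at 0.13 ± 0.05. At an unadjusted p under 0.05 this list held 3 higher genes and 1 lower gene. Of the lipogenic regulators 13 of 15 were lower (median -0.05), and SREBF1 stood at -0.08 ± 0.05. CD14 at 0.25 ± 0.06 (5 of 6 cows higher) and PRDX1 at 0.27 ± 0.07 (6 of 7) passed adjusted over their lists alone. The adjusted p was 0.00261 over the inflammation list for CD14 and 0.0103 for PRDX1. With CD14 counted in the myeloid list too that makes 3, against 0 over all probes and without correction over the 26 lists. The direction of the test was up while the median was below 0 for the endothelial (-0.02), cholesterol (-0.04) and lymphocyte lists (-0.0022). It was up with a mean of -0.01 for inflammation, and down with a mean above 0 for the adipocyte (0.0026) and class II lists (0.0050). With an estimated correlation the smallest adjusted p was 0.913, and with fry 0.268 (0.850 for its mixed test).

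The count of 16 probes that differed was 16 with cow as a random block and 0 with differences taken within the 7 shared cows (767 at an unadjusted p under 0.05). With image folder as a batch term it was 0 (1006; smallest adjusted p = 0.0807). AARSD1 differed by 0.42 ± 0.08 before and after that term, USP12 by 0.23 ± 0.04 both times and ERCC6L2 by 0.44 ± 0.08 and 0.41 ± 0.08. Over the 16 probes the values were 0.921 to 1.06 times those without it and the SE was larger in 14 (median 1.07 times), with the same loss of degrees of freedom. The unadjusted p-values rose in 13 of 16. All 16 calls ended, also where p fell, as for SNED1 (limma, unadjusted p = 9.40e-05 before and 2.39e-05 after). Over all probes the SE was 1.03 times that without the term in the median. With feeding period as covariates the count was 0 (871, smallest adjusted p = 0.0590). The values were then 0.933 to 1.08 times those without the term, with a larger SE in 12 of 16. USP12 then differed by 0.22 ± 0.04 and AARSD1 by 0.42 ± 0.08. Within image folder 1, with 3 cow values of each comparison, the count was 0 (546). It was 0 without LFSO replicate 1, 3, 5, 6 or 8 and without HFRS replicate 1, 2, 6 or 8; it was 3, 6 and 26 without LFSO replicates 2, 4 and 7, and 44, 10 and 5 without HFRS replicates 4, 5 and 7. Without both values of a shared cow it was 0 or 1, except for 86 without the cow of LFSO replicate 7 and HFRS replicate 4.

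The comparison of HF with LF, the control diets, was made between arrays in the 7 cows present in both comparisons, and no gene passed. The genes of smallest p were ZNF503, a transcriptional repressor, at -0.59 ± 0.11 (SE, n = 7; 7 of 7 cows lower in HF, limma, adjusted p = 0.999) and GHRHR, the receptor of growth hormone releasing hormone, at -0.56 ± 0.12 (7 of 7). COL4A1, a collagen of basement membranes, stood at -0.49 ± 0.12 (7 of 7), HIBADH, an enzyme of valine breakdown, at -0.47 ± 0.12 (6 of 7) and LAGE3 at -0.35 ± 0.10 (7 of 7). Among those higher in HF were TTC12 at 0.58 ± 0.14, the membrane skeleton protein EPB41 at 0.56 ± 0.14, LRRC4B at 0.54 ± 0.14, USP21 at 0.50 ± 0.14 and ZSCAN21 at 0.33 ± 0.08. By limma 0 of 6477 probes passed, and 196 had an unadjusted p under 0.05, where chance alone would give 324. In simulated data for this comparison 0% of changes at log2 0.25, 6% at 0.5, 50% at 0.75 and 76% at 1 were recovered. These too are shares with 200 probes changed at once. Over 10 further draws the ranges were 4% to 24%, 40% to 64% and 72% to 88% for the last 3 sizes, and 0% each time at 0.25. The count was 0 with image folder as a batch term (204) and within image folder 1 (194).

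By camera 0 of 26 lists passed in HF vs LF (smallest adjusted p = 0.518, 2 lists at an unadjusted p under 0.05). Of the endoplasmic reticulum stress genes 11 of 16 were higher (median 0.07), and of the fibroblast and matrix markers 6 of 9 were lower (median -0.09). COL4A1 passed adjusted over the latter list alone (adjusted p = 0.0168, 7 of 7 cows lower) as the 1 member to do so, against 0 over all probes. With no correction over the 26 lists, this too can arise by chance. The test and the median differed in sign for the secretory epithelial (up, -0.06), ribosomal (down, 0.00036), interferon (up, -0.0014), cholesterol (down, 0.03) and lipogenic regulator lists (down, 0.00088). With an estimated correlation the smallest adjusted p was 0.991, and with fry 0.218 (0.981 for its mixed test).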

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

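Tests of explanations in this part were set before the result they measure was seen, with exceptions. The removal of the dye profile, and the comparisons of values before and after the folder and period terms, were chosen after seeing the data. Fisher's exact tests of the highest other split were run after that split was found.

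Single cows stood far from the others in 7 of 84 sets of values (8.33%), where chance alone marks about 1 in 20. LFSO replicate 5 held 3 of them. Its swapped arrays had the highest correlation of the 17 cow values, at -0.0937 and at 0.461 with the dye profile subtracted. In that cow FASN was 0.22 and LPL 0.47 (log2, LFSO over LF), where the other cows were lower in 8 of 8 and in 7 of 8, and LALBA was 0.84. Without it FASN stood at -0.15 (adjusted p = 0.207, lower in 8 of 8 cows), LPL at -0.12 and LALBA at -0.03, and none of them passed. CD36 stood apart at -0.14 in LFSO replicate 4 and at -0.35 in HFRS replicate 5, ACSL1 at -0.28 in LFSO replicate 6 and TET2 at -0.34 in HFRS replicate 5, without which its HFRS value was -0.10 instead of -0.13. No biological explanation was tested for these cows.

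The supplement effects differed at 16 probes in the test of the difference itself, LFSO vs LF minus HFRS vs HF. On the log2 scale the difference was 0.44 for ERCC6L2, 0.42 for AARSD1, 0.42 for MTMR4, 0.35 for ITGB2, 0.34 for TALDO1, 0.32 for SNED1, 0.28 for TRPM2 and 0.28 for PARPBP. It was 0.27 for IFT27, 0.24 for ALDH3B1, 0.24 for TET2, 0.23 for USP12, 0.22 for EEF1B2 and -0.24 for NSUN5. Of 100 splits of the cow values into the comparisons, the real one included, 3 gave as many probes. This argues against chance for this count but does not exclude it. At an unadjusted p under 0.05, 7 of 100 splits gave as many as the real 926, the highest other 1731, which leaves chance open. The highest other split for the count gave 349 probes, which points to a structure of the samples that was not identified. Its first arm held 5 of 6, 1 of 3, 0 of 3 and 3 of 5 values of image folders 1 to 4. For periods 1 to 4 of the supplemented diet it held 1 of 5, 2 of 4, 3 of 5 and 3 of 3. Fisher's exact test gave p = 0.117 for folder and 0.247 for period. With so few values per folder or period, these tests cannot exclude a tie to either. With image folder as a batch term 0 probes passed (smallest adjusted p = 0.0807). The difference was 0.23 ± 0.04 for USP12 before and after the term, and over the 16 probes it was 0.921 to 1.06 times its value without it. The SE was larger in 14 of 16 and the residual degrees of freedom fell from 15 to 12, where the adjusted p-values had been 0.0360 to 0.0492. The unadjusted p-values rose in 13 of 16, which is likely in a refit of probes picked for a small p. Why the calls ended was not tested. Dye bias left after averaging is not excluded either: with the dye profile removed 5 probes passed, 3 of them among the 16. Across probes the LFSO effect correlated with the dye profile at -0.180 and the HFRS effect at 0.291. Among 100 splits that part the 7 shared cows as the real one does, 1 gave as many, and the highest other gave 11 (3 and 1189 at an unadjusted p under 0.05).

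The effects of the supplements were correlated below 0 across probes (r = -0.373 over 7226 probes, which are not independent replicates). Chance cannot be excluded, since 7 of 100 splits that exchange the diets within cows gave a correlation as far from 0, the highest other at 0.520. Dye bias that follows the mean dye profile is argued against as the whole cause: with that profile removed r was -0.339. Other dye bias is not covered. For image folder batch the test does not decide: r with folder as a term was -0.292, between the bounds set in advance for either outcome. A response that differs between the oils or the forages is open and untested as a cause, because supplement and forage changed together in this design.

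In LFSO vs LF 11 probes passed, and 1 of 100 splits, the real one, gave as many. The highest other gave 1, which argues against chance for this count. It was 0 with image folder or feeding period as a term and with the LFSO cow values alone (smallest adjusted p = 0.0583, 0.0559 and 0.0963), where TALDO1 stood at 0.26 ± 0.05, 0.30 ± 0.05 and 0.27 ± 0.05 (0.27 ± 0.05 before). The SE was larger in 10, 9 and 6 of the 11 and fewer degrees of freedom were left. The wider excess of 874 probes at an unadjusted p under 0.05 is weaker evidence: 7 of 100 splits gave as many, the highest other 1185, and chance cannot be excluded. With the dye profile removed 899 probes were left and with image folder as a batch term 830, which argues against dye bias and image folder batch as the whole cause of the excess. Within image folder 1 alone, with 3 cows, 357 of 7222 probes were left. An effect of sunflower oil on many genes by small amounts may stand behind the excess and stays a hypothesis.

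Control spots outside the comparisons gave signal. Spots of the Alien oligos were detected in 98.0% of cases, those of the Rn control oligos in 88.1% and those of the other control oligos in 99.7%, against 4.37% of blank spots.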

How the results depend on the processing

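The settings named as added below were chosen after seeing the data. In LFSO vs LF the 11 probes became 0 with print-tip loess, image folder as a batch term, image folder 1 alone, feeding period as covariates, the 7 shared cows alone or that comparison's cows alone, and 1 with the signal median. They became 17 with a strict filter on dim probes, which tests fewer probes (5566). The count was also 17 with all arrays and a dye coefficient, where a cow's 2 arrays counted nearly as separate replicates (consensus correlation 0.0346). Among the added settings they became 2 with spots marked empty kept and 0 with only swapped pairs correlated above 0 once the dye profile was removed, which leaves 6 cow values of LFSO and 3 of HFRS. Leaving out one cow value at a time gave 0 to 20. With both values of a shared cow left out, also added, they became 0, 5, 3, 1, 1, 42 and 18 without the cows of LFSO replicates 1, 2, 3, 5, 6, 7 and 9.

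The 16 probes of the difference became 0 with median centring, image folder as a batch term, image folder 1 alone, feeding period, the 7 shared cows alone and cow as a replicate block by differences within cows; each of the last 3 named subsets or terms leaves fewer values or degrees of freedom. They became 4 with normexp at offset 0, 6 with print-tip loess, 9 with the signal median, 25 with the strict filter, 26 with arrayWeights, 42 with the authors' table and 48 with all arrays. Of the 42, 12 were among the 16. Among the added settings they became 4 with spots marked empty kept, 5 with the dye profile removed and 0 with only those correlated pairs. Of the 5, 3 were among the 16. Leaving out one cow value gave 0 to 44, and leaving out both values of the same 7 cows gave 0, 1, 0, 0, 1, 86 and 0. Except where a smaller set of probes or cows was named, the cause was not tested.

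In HFRS vs HF the count was 0 in 44 of 46 settings (left-out cow values 0 to 1, and 1 without both values of the cow of HFRS replicate 4). In HF vs LF and HFRS vs HF 64 of 64 and 100 of 100 splits gave at least the real 0, with 38 and 1 as the highest other; every split reaches a count of 0, so this decides nothing about chance. HF vs LF gave 0 in all 22 settings, with 111 to 262 probes at an unadjusted p under 0.05, and no gene list passed under any setting run. The called probes of the 9 named genes in LFSO vs LF kept their direction in all 405 values over these settings and stayed past the threshold in 175. Those of the 14 genes of the difference kept it in all 643 and stayed past the threshold in 224. The probes were picked for a small p in the same cow values, so a kept direction was near certain and is no support. No filter on dim probes removed no tested probe and so tests nothing. Median signal over background was 2.52 to 5.54 in Cy3 and 7.04 to 15.5 in Cy5. In LFSO vs LF the median SE was 0.0364 for the dimmest 2409 probes and 0.0413 for the brightest 2409.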

Other observations

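The control diets, HF vs LF, were compared between slides, and were less precise: the median SE over probes was 0.135 (log2), against 0.0377 in LFSO vs LF and 0.0404 in HFRS vs HF. None of the milk and immune genes below passed limma's test in the 7 cows. Among myeloid markers C1QA, a chain of complement C1q, stood at 0.88 ± 0.27 (log2, SE; 5 of 6 cows higher in HF) and AIF1, a macrophage protein, at 0.42 ± 0.14 (7 of 7). CSF1R, a receptor of the same cells, stood at -0.20 ± 0.14. As a whole that list did not pass: 7 of 11 genes were higher, the median was 0.0068 and camera's adjusted p was 0.773. Of the milk fat globule and lipid droplet genes 6 of 10 were lower (median -0.09, adjusted p = 0.773). The mucin MUC15 of that list stood at -0.42 ± 0.14 (5 of 7 cows lower), DGAT1 at -0.44 ± 0.21 (5 of 7) and LPL at -0.17 ± 0.12 (6 of 7). ME1, which supplies NADPH, stood at 0.21 ± 0.08 (6 of 6 higher), and LALBA at 0.59 ± 0.39 (5 of 7).

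A cow's own deviations from the mean effect in one comparison were little related to its deviations in the other. Over the 7 cows in both comparisons this correlation across probes had a median of -0.00854 (lowest -0.233, highest 0.471), against -0.0131 over 42 pairs of different cows.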
